A study of Mus musculus with 2 samples.

How the data were processed

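The 2 mouse CD4+ T cell libraries come from chromatin immunoprecipitation with a GATA3 antibody, 1 labelled TGF-β plus IL-4 and 1 with no treatment named. Per the labels' protocols, crosslinked chromatin was sonicated to between 200 and 300 bp, the libraries were amplified for 17 cycles and fragments of about 220 bp with adaptors were cut from a gel. CASAVA 1.0 and Bowtie2 are listed as tools and mm9 as the build per the submitters' processing notes, which give them here without role or settings. The deposited files hold 1 line per aligned read, with chromosome, start, end, length, mapping quality and strand. The mapping quality is a score per read that the authors deposited with it, and it ran from 11 to 42 in both files. The file names state a filter on mapping quality and the removal of duplicates, and the files bear this out: 0 reads shared a position and strand with another read of the same library. Removing duplicates limits each position to 1 read per strand, which compresses differences at the strongest sites.

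All counts of reads were made here from those files. Reads on chromosomes 1 to 19, X and Y were used: 22963959 in the library with no treatment named and 15561681 in the TGF-β plus IL-4 library. The 1117 and 1161 reads on the mitochondrial chromosome were left out. The fragment length was taken as the distance with the highest strand cross-correlation, 125 and 130 bp. Since no peak list and no control library was used here, peaks were called with code written for this purpose in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Reads were extended to the fragment length and the coverage at every 10 bp was set against a Poisson rate, the larger of the rate over the covered genome (2369270000 bp in bins of 1 kb with a read) and the rate in the surrounding 10 kb. Positions at a Benjamini-Hochberg q under 0.01 over covered positions were merged across gaps of up to 100 bp. Peaks of at least 100 bp with at least 20% of reads on each strand were kept. Without an input library, open chromatin and repeat copies missing from the assembly can also give peaks. The deeper library was thinned at random to 15561681 reads for peak calling, because peak number grows with depth. Enrichment tests of this kind compare a library with its own surroundings, not the conditions.

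Peaks of both libraries that overlapped by at least 1 bp were merged to union peaks, and all reads whose fragment centre fell in a union peak were counted and expressed as RPM, per 1000000 reads of the library. The ratio of the libraries carries an exact Clopper-Pearson 95% interval of the split of the reads. Shares of reads carry Wilson 95% intervals. These intervals, and the floor of 3 reads used where a library had 0, cover counting error only, and PCR reads without molecular identifiers are not independent molecules. A peak counted as higher or lower at a ratio of at least 2 or at most 0.5 with an interval that left out 1.

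The procedures were tested on simulated data. On a simulated chromosome at the thinned depth the caller found 0 of 300 sites with 4-fold coverage at the summit, 49 of 300 at 8-fold, 256 of 300 at 16-fold and 300 of 300 at 32-fold, with 0 false peaks. The simulated background was uniform, so the 0 does not cover false peaks from open chromatin or repeats in the real libraries. In counts drawn for the comparison of the 2 libraries at the 65709 union peaks, the size rule recovered 41 of 100 peaks changed 2-fold and 98 of 100 changed 4-fold, and it marked 1399 unchanged peaks. A 2-fold change lies on the bound of the rule itself, so many such peaks fall short of it by counting error at any depth.

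Regions named in the text followed a rule fixed before the data were examined: the 3 peaks with the highest RPM in each library, and the 8 highest and 8 lowest ratios among peaks past the size rule, ranked by the interval bound nearest to 1, leaving out regions with 80% of reads on one strand. The alternatives fixed at the same time were a stricter q of 1e-05, all reads, a second thinning, a 5 kb background rate, a minimum enrichment of 5, a fragment length of 200 bp, no strand rule, overlap by 50% of both peaks, other scalings, subtraction of the background within 10 kb, and a ratio of 1.5. Lists of T helper genes and motif searches had also been planned, on condition of an mm9 annotation and sequence. The gene table at hand is of GRCm38, positions were not converted between builds, and these analyses were not made. Figures were drawn with matplotlib 3.10.9.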

Results

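GATA3, the zinc-finger transcription factor that directs T helper 2 differentiation, was mapped by chromatin immunoprecipitation and sequencing in mouse CD4+ T cells. The cells were of the C57BL/6 strain and were naive, CD25-negative and CD62L-positive at isolation. The series holds 2 libraries. One comes from cells labelled as stimulated with TGF-β and IL-4, for which the protocol gives 2 ng/ml TGF-β1 and 10 ng/ml IL-4 with antibodies to CD3 and CD28 at 1 µg/ml each. The other carries no treatment name. The culture protocol, which is the same text for both libraries, covers TGF-β1 given with and without IL-4, so the labels leave open whether the second library stands for cells given TGF-β1 alone or for unstimulated cells. It is called here the library with no treatment named. The series asks how GATA3 binding differs after stimulation with TGF-β1 and IL-4. There is 1 library per condition and no input or control antibody library was used here, so no difference between the conditions has a replicate check and no p-value for one is given. Regions are identified by their mm9 position, because no mm9 gene annotation or sequence was used here.

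Both libraries carried the strand pattern of a sharp chromatin immunoprecipitation profile. The library with no treatment named held 22963959 reads on chromosomes 1 to 19, X and Y, and the TGF-β plus IL-4 library held 15561681. All reads were 25 bases long. In the library with no treatment named the correlation between the strands was highest at a distance of 125 bp, at 0.0236, which was 6.75 times its value at 1000 bp. In the TGF-β plus IL-4 library the maximum lay at 130 bp, at 0.0295, which was 9.05 times the value at 1000 bp. In each library the correlation at the read length was lower than at the fragment length, at 0.0125 and 0.0151. No position held more than 1 read on a strand, so a summit could hold at most 250 fragments in one library and 260 in the other.

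**Figure D1:**
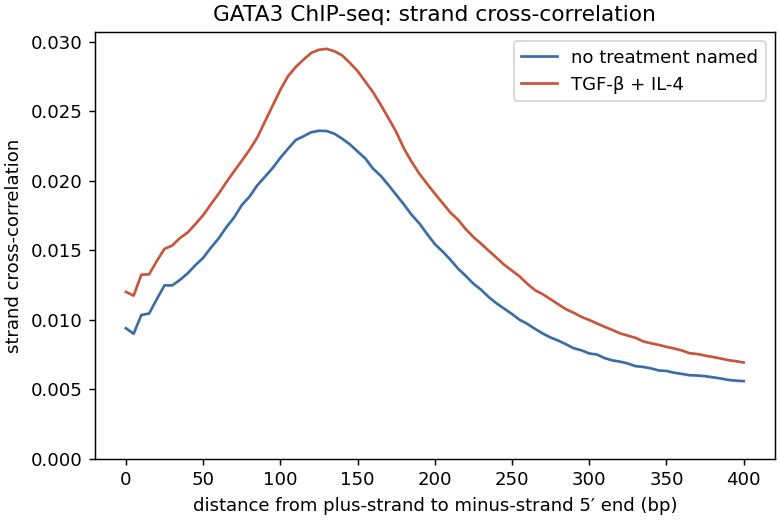
Correlation between plus-strand and minus-strand 5′ ends (vertical axis, no unit) against the distance between them in bp (horizontal axis), averaged over chromosomes 1 to 19, 1 line per library. The maximum lies at 125 bp for the library with no treatment named and at 130 bp for the TGF-β plus IL-4 library, where it reaches 0.0295.

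At equal depth the TGF-β plus IL-4 library had more GATA3 peaks and a larger share of its reads in them. With both libraries at 15561681 reads, 55665 peaks were called in the TGF-β plus IL-4 library and 36217 in the library with no treatment named, a ratio of 1.54. The peaks held 12.1% of the reads of the TGF-β plus IL-4 library (Wilson 95% interval 12.1% to 12.2%) and 7.0% of those of the other (6.99% to 7.01%). Over the union of both peak sets the shares were 12.7% and 8.66%. These intervals cover counting error only. With all reads the deeper library with no treatment named had 55641 peaks, almost the number of the shallower one, so the difference in peak number appears only when depth is matched.

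Most peaks of the library with no treatment named were also called in the TGF-β plus IL-4 library, while the larger part of the TGF-β plus IL-4 peaks had no counterpart. Of the 36217 peaks of the library with no treatment named, 26106 (72.1%) overlapped a TGF-β plus IL-4 peak by at least 1 bp. Peaks placed at random in covered parts of the same chromosomes overlapped at a mean rate of 0.944%, and at most 1.01% over 20 placements. Of the 55665 TGF-β plus IL-4 peaks, 25779 (46.3%) overlapped a peak of the other library and 29886 did not. The shared sites were the strong ones. In the TGF-β plus IL-4 library, overlapping peaks had a median summit of 25 fragments and a median enrichment of 12.8 over the local background, and peaks without overlap had 12 fragments and 8.68. In the library with no treatment named the medians were 19 fragments and 11.6 for overlapping peaks, and 11 fragments and 9.16 for the 10111 peaks without overlap. When a single library was parted at random into 2 equal subsets of 7780840 reads and peaks were called in each, the subsets overlapped for 66.0% and 65.4% of peaks in the library with no treatment named and for 64.9% and 64.3% in the TGF-β plus IL-4 library. At that same depth 72.2% of the peaks of the library with no treatment named overlapped a TGF-β plus IL-4 peak, and 44.4% of the TGF-β plus IL-4 peaks overlapped in the other direction. At that depth the library with no treatment named had 18973 peaks and the TGF-β plus IL-4 library 30667, and lists of unequal length can raise the first of these shares and limit the second.

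With scaling by total reads, RPM was higher in the TGF-β plus IL-4 library at most of the 65709 union peaks. Of all union peaks, 45.5% were called in that library alone, a choice that by itself favours ratios over 1. The median log2 ratio of RPM (reads per 1000000 reads of the library, TGF-β plus IL-4 over no treatment named) was 0.68 over all union peaks and 0.42, a ratio of 1.34, over the 25712 peaks called in both libraries. A peak was counted as higher or lower when its ratio was at least 2 or at most 0.5 and its exact 95% interval, from the binomial split of its reads, left out 1. By that rule 16699 peaks (25.4%) were higher and 2406 (3.66%) were lower in the TGF-β plus IL-4 library. Of the 29886 peaks called in the TGF-β plus IL-4 library alone, 13379 (44.8%) were higher. Of the 10111 called in the library with no treatment named alone, 2077 (20.5%) were lower. Among the shared peaks 3312 (12.9%) were higher and 329 (1.28%) were lower, and 76.5% had a ratio over 1. The same rule applied between 2 random and equal subsets of a single library at these union peaks gave 1299 peaks (642 higher, 657 lower) in the library with no treatment named and 1375 (726 higher, 649 lower) in the TGF-β plus IL-4 library, against 19105 between the libraries. The subsets held fewer reads than the libraries, so these numbers are not at equal depth. When peaks were called in 7780840 reads of each library and counted in 7780840 others, 4618 (12.8%) of 36102 union peaks were higher and 499 (1.38%) lower. At those 36102 peaks subsets of the library with no treatment named, of 7591559 and 7591560 reads, gave 358 and 327, and binomial draws at a ratio of 1 gave 343 and 359. Called and counted in the same reads at 7780840 per library, 7093 of 35917 union peaks were higher and 1170 lower. Choosing and counting peaks in the same reads thus raised both numbers, and the 25.4% and 3.66% above rest largely on such reads.

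The split between higher and lower peaks depended on how the libraries were scaled. Of the peaks past the rule, 87.4% were higher with scaling by total reads and 90.4% with scaling by the reads outside peaks, which raised the median log2 ratio of all peaks by 0.10. When the libraries were scaled so that the median ratio of the shared peaks was 1, 7644 peaks were higher and 5471 lower, so that 58.3% of the changed peaks were higher. With that scaling the shared peaks alone gave 828 higher and 1272 lower. Of the peaks called in the TGF-β plus IL-4 library alone, 6815 (22.8%) were then higher. Of those called in the library with no treatment named alone, 4193 (41.5%) were then lower. The ratios of the named peaks were therefore also computed under each scaling.

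**Figure D2:**
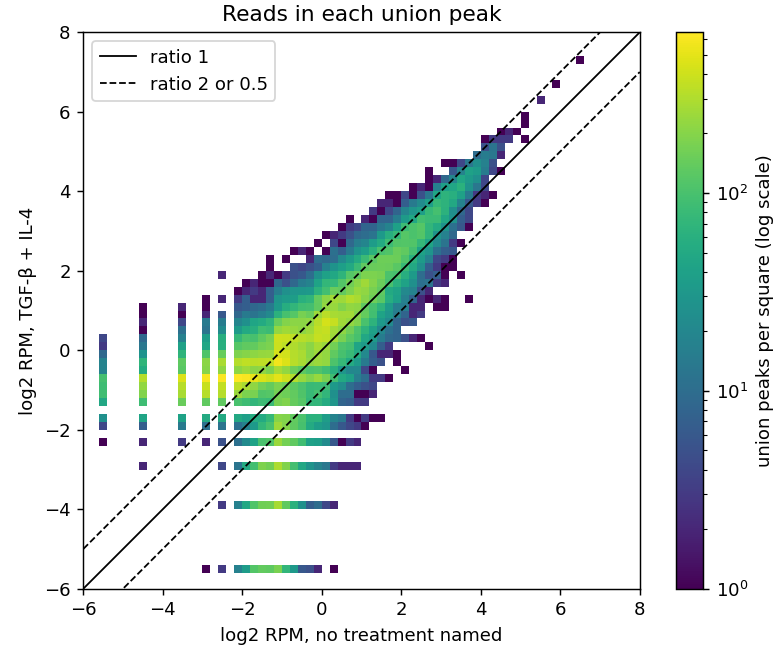
Log2 RPM of each of the 65709 union peaks in the library with no treatment named (horizontal) and in the TGF-β plus IL-4 library (vertical). Colour gives the number of peaks per square on a log scale, the solid line a ratio of 1 and the dashed lines ratios of 2 and 0.5, and peaks with 0 reads are drawn at the left or lower edge. The cloud of strong peaks lies above the solid line and stays mostly within the dashed lines.

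**Figure D3:**
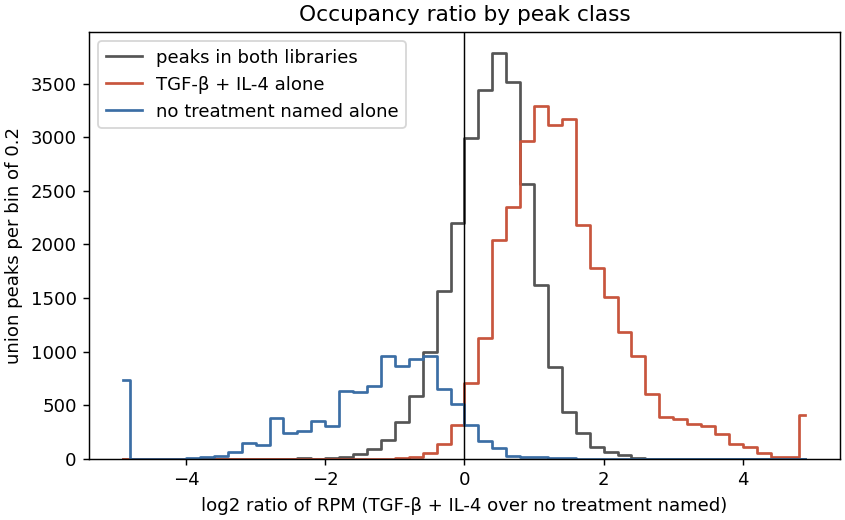
Number of union peaks per bin of 0.2 (vertical axis) by log2 ratio of RPM, TGF-β plus IL-4 over no treatment named (horizontal axis), for peaks called in both libraries or in 1 alone. Values beyond 5 are placed in the outermost bins. The shared peaks centre at 0.42, to the right of 0.

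The spread of ratios was described by peak strength. In the top 20% of union peaks by reads, from 2.02 to 121 RPM averaged over the libraries, 20.1% were higher and 1.18% lower, the median log2 ratio was 0.58, and 80% of the values lay between -0.18 and 1.26. In the bottom 20%, from 0.0653 to 0.420 RPM, the same range ran from -2.61 to 3.02, around a median of 1.15, with 24.3% of peaks higher and 7.58% lower. Peaks of the bottom 20% held few reads and 0.112% of them were called in both libraries, against 95.5% in the top 20%, so counting error and the choice of peaks in 1 library widen their spread. The 3 peaks with the most reads in each library were the same 3, all within a short stretch of chromosome 17. The first, from 39980061 to 39981860, held 2105 reads (91.7 RPM) in the library with no treatment named and 2331 (149.8 RPM) in the TGF-β plus IL-4 library, a ratio of 1.63 (95% interval 1.54 to 1.73). The second, from 39982001 to 39983270, had a ratio of 1.68 (1.56 to 1.81) and the third, from 39984611 to 39985740, a ratio of 1.72 (1.59 to 1.87). At these 3 peaks between 47.2% and 64.8% of all positions on either strand already held a read, and 52.5% to 77.6% of their reads had the top mapping quality, against 87.8% and 88.3% in the whole libraries. Without an input library, reads from repeat copies missing from the assembly cannot be told apart from GATA3 binding at these 3 peaks.

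The 8 peaks with the highest ratios by the fixed ranking were all called in the TGF-β plus IL-4 library alone and lay on 7 chromosomes. They held 19 to 79 reads in that library and 0 to 9 in the other. These peaks were picked out of 65709 union peaks in the same reads that gave their ratios. Such a choice tends to raise the ratios, and the intervals do not allow for it. On chromosome 13 from 37382701 to 37382940 there were 34 reads against 1, a ratio of 50.2 with an interval of 8.42 to 2039. A smaller group of fragments just beside this peak was present in both libraries at similar coverage. On chromosome 4 from 3486981 to 3487200 there were 58 reads against 4, a ratio of 21.4 (7.92 to 81.2), and on chromosome 9 from 81954011 to 81954240 there were 57 against 4, a ratio of 21.03 (7.78 to 79.8). On chromosome 18 from 32318321 to 32318460 the reads numbered 30 against 1, a ratio of 44.3 (7.36 to 1806). On chromosome 3 from 59528431 to 59528790 they numbered 79 against 9, a ratio of 13.0 (6.49 to 29.4). The other 3 had 0 reads in the library with no treatment named. Set against a floor of 3 reads in that library, the peak on chromosome 1 from 139809941 to 139810170, with 20 reads, was at least 9.84-fold higher, and the lower limit of its exact interval, which also covers the error of the 20 reads, was 7.29. The peaks on chromosome 3 from 137954871 to 137955010 and on chromosome 7 from 121610041 to 121610230, each with 19 reads, were at least 9.35-fold higher against that floor, with a lower limit of 6.89 by the exact interval.

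The 8 peaks with the lowest ratios included 2 sites called in both libraries. All 8 were picked in the same way as the highest, which tends to lower their ratios, and the intervals do not allow for it. On chromosome 12 from 110656901 to 110657230 the TGF-β plus IL-4 library had 17 reads and the library with no treatment named 148, a ratio of 0.17 (0.0962 to 0.281). On chromosome 7 from 4896451 to 4897190 there were 41 reads against 298, a ratio of 0.203 (0.143 to 0.282). The peak on chromosome 5 from 37461651 to 37461840 had 5 reads against 62, a ratio of 0.119 (0.0373 to 0.293). The peak on chromosome 7 from 88255431 to 88255600 had 2 against 44, a ratio of 0.0671 (0.00788 to 0.257), and the peak on chromosome 14 from 21025341 to 21025580 had 2 against 40, a ratio of 0.0738 (0.00864 to 0.285). The remaining 3 had 0 reads in the TGF-β plus IL-4 library. Against a floor of 3 reads there, the peak on chromosome 3 from 152786691 to 152786890, with 29 reads, was at least 6.55-fold lower, the peak on chromosome 6 from 36849361 to 36849590, with 22 reads, at least 4.97-fold lower, and the peak on chromosome 14 from 121492911 to 121493090, with 21 reads, at least 4.74-fold lower. The upper limits of their ratios by the exact interval were wider, at 0.20, 0.269 and 0.283. In the chromosome 3 peak 0% of the reads had the top mapping quality and the median distance between the strands was 22.5 bp, and in the chromosome 6 peak the values were 45.5% and 26 bp, against the library's fragment length of 125 bp. The chromosome 14 peak from 121492911 had 76.2% and 52.5 bp. Among the highest-ratio peaks the one on chromosome 1 from 139809941 had 85.0% and 48 bp, against a fragment length of 130 bp. None of the 19 regions named here changed direction under the scaling, thinning and background alternatives tried. The scalings move every log2 ratio alike, up by 0.10 or down by 0.42. The smallest log2 ratio in size among these regions was 0.71, so no scaling could have turned any of them. Thinning reused the same reads.

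**Figure D4:**
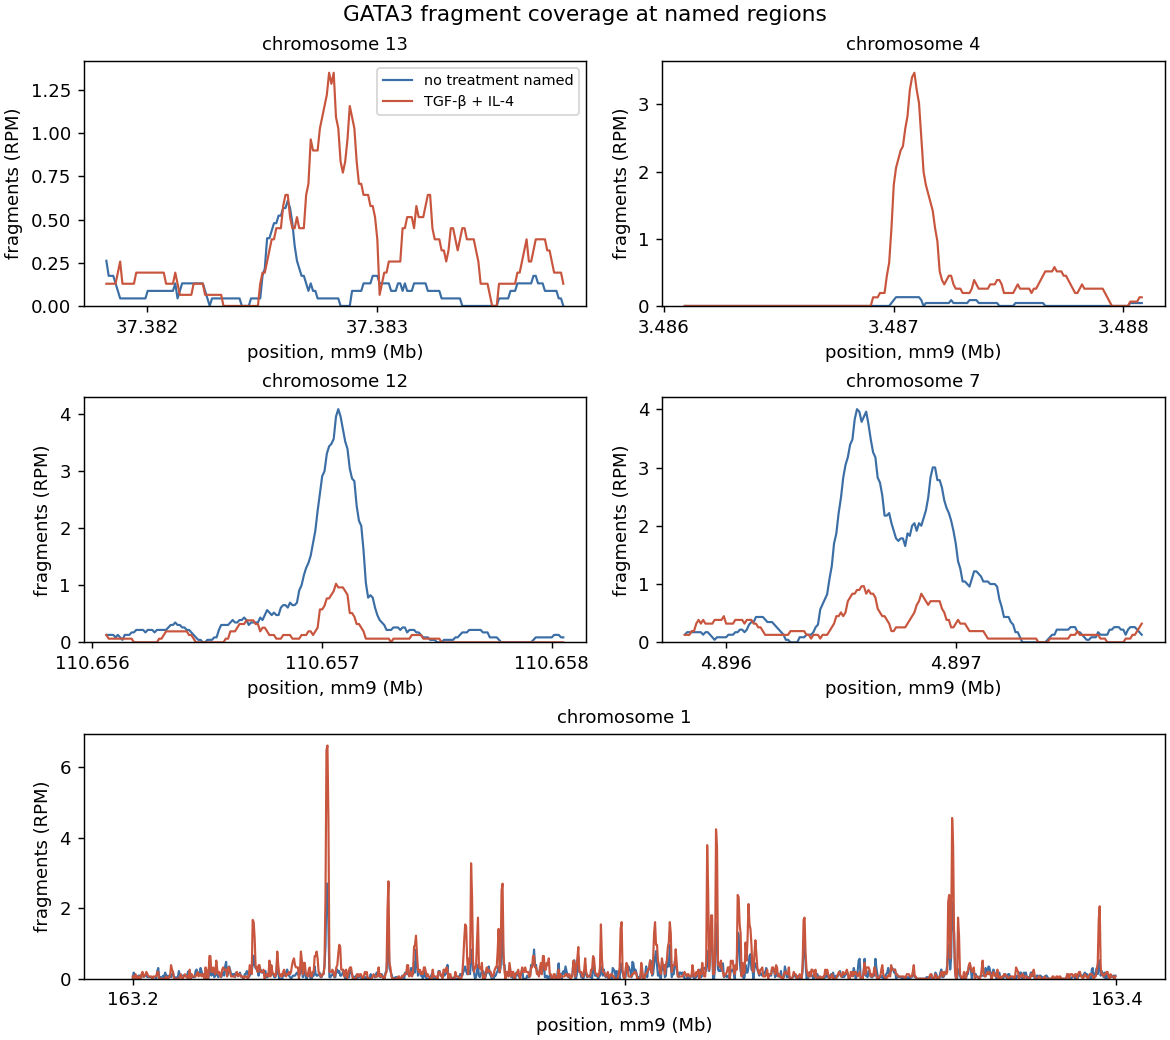
Fragment coverage in RPM (vertical axes) along mm9 positions in Mb (horizontal axes) in the library with no treatment named (blue) and the TGF-β plus IL-4 library (red). The upper panels show regions on chromosomes 13 and 4 with ratios of 50.2 and 21.4, the middle panels regions on chromosomes 12 and 7 with ratios of 0.17 and 0.203, and the lower panel 2 neighbouring windows of 100 kb on chromosome 1, drawn as the highest value per 200 bp, where most peaks are taller in the TGF-β plus IL-4 library.

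Every autosome and the X chromosome had more higher than lower peaks with scaling by total reads. On the autosomes the share of union peaks past the rule as higher ranged from 23.4% on chromosome 17 to 27.3% on chromosome 6, and the share lower ranged from 2.93% on chromosome 19 to 4.31% on chromosome 6. Peak density was highest on chromosome 11, with 38.8 union peaks per Mb of covered sequence, and on the autosomes lowest on chromosome 14, with 24.1. The X chromosome had 9.06 union peaks per Mb. Of its 1201 union peaks, 28.9% were higher and 2.75% lower. On the Y chromosome, with 37 union peaks, 4 were higher and 1 lower, and the median log2 ratio was -0.16, against 0.85 on X. The share of X in all reads was 2.93% in the TGF-β plus IL-4 library and 2.59% in the other.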

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

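Of the tests below, the one on mapping quality at single peaks, the one on reads of the Y chromosome and the subsets of 1 library with peaks called anew and the counts in reads not used for peak calling were chosen only after related results had been seen.

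The mitochondrial chromosome, left out of every comparison, held 1117 reads in the library with no treatment named and 1161 in the TGF-β plus IL-4 library. The mapping quality column, which entered no ratio except as a filter in 1 alternative, showed 1210 union peaks in which most reads were below the top quality. They made up 3.24% of the peaks called in the library with no treatment named alone, 1.63% of those called in the TGF-β plus IL-4 library alone and 1.54% of the shared peaks. Over the 8 named peaks with the lowest ratio the median share of reads at the top quality was 84.8%, and over the 8 with the highest ratio 94.7%. Most of the 8 lowest-ratio peaks were thus not made up mainly of reads under the top quality, but a median cannot speak for single peaks. The peaks on chromosome 3 from 152786691 and on chromosome 6 from 36849361 stood apart with 0% and 45.5%. For these, reads that differ from the reference stay open.

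With scaling by total reads 19105 union peaks passed the size rule between the libraries. Of these, 16699 were higher in the TGF-β plus IL-4 library. Counting error around a ratio of 1 does not account for the number of higher peaks. At the main union peaks 2 random and equal subsets of 1 library gave at most 1375 peaks past the rule in both directions. The subsets held fewer reads than the libraries, and those peaks were chosen partly on differences between the libraries. The 1375 and the 19105 are therefore not on equal terms. With peaks called anew at 7780840 reads, subsets of 1 library gave at most 6.0% of union peaks, against 23.0% between the libraries. In reads not used to choose the peaks 4618 were higher, against at most 359 in 1 direction from counting at a ratio of 1. In the reads not used to choose the peaks 499 were lower, more than the 359 but less than the 2 times set beforehand as the bound. The draws behind the 359 used a ratio of 1, while the median ratio at shared peaks was 1.34. Draws around a ratio over 1 would give fewer lower peaks, so the 359 cannot set what counting gives here. Counting error stays open for the lower peaks in those reads, since such draws were not made for them. At the shared peaks a single common factor does not account for the number past the rule either. After scaling to a median ratio of 1 there were 2100 shared peaks past it, against 310 in binomial draws with 1 common ratio. That scaling turned 3312 higher and 329 lower shared peaks into 828 and 1272. Of the higher peaks, 13379 were called in the TGF-β plus IL-4 library alone. For such peaks a common factor together with counting error was not tested. A stronger pull-down in the TGF-β plus IL-4 library may account for the general shift, a median ratio of 1.34 at shared peaks, and it cannot be told apart from more GATA3 on chromatin because no spike-in, input or replicate sets the scale. Variation between any 2 such libraries, whatever their treatment, also stays open for the peak-by-peak differences, as does an effect of the stimulation itself.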

How the results depend on the processing

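No paired analysis was possible because each condition has 1 library, and leaving out a replicate was not possible for the same reason. The gene lists and motif searches were not run, for lack of an mm9 annotation and sequence. Of the alternatives below, the correction for 1 read per position and the removal of peaks with mostly lower mapping quality were chosen after seeing the data. None of the 19 named regions and none of the main counts over all union peaks changed direction, but among the shared peaks alone 3312 higher and 329 lower became 828 higher and 1272 lower with scaling to their median. The scalings could not have turned the named regions, whose log2 ratios were all larger in size than the largest shift by scaling. With q under 1e-05 there were 16707 peaks in the library with no treatment named and 26085 in the TGF-β plus IL-4 library, of which 13874 of the latter were shared, 12211 were in the TGF-β plus IL-4 library alone and 2737 in the other alone. The shares of reads were then 4.87% and 8.7% in each library's own peaks and 6.06% and 8.98% in union peaks, and 8158 union peaks were higher and 861 lower. With all reads the library with no treatment named had 55641 peaks, 23331 of them without overlap, and the shares of reads were 8.38% in its own peaks and 9.52% (no treatment named) and 13.2% (TGF-β plus IL-4) in union peaks. A fragment length of 200 bp gave 16180 peaks without overlap in the library with no treatment named. Scaling to a median ratio of 1 at shared peaks gave 7644 higher and 5471 lower peaks and a median log2 ratio of 0.26, and scaling by reads outside peaks gave a median of 0.79. The scalings move the median by construction, and the cause of the other shifts was not tested. The other 48 values for the main results stayed within 1.5 times their value, or within 0.1 for the median log2 ratio, and the ratio of peak numbers at equal depth ranged from 1.37 to 1.56. Correcting for 1 read per position gave 17274 higher and 2689 lower peaks. Depth limits the weak sites: in simulations at the thinned depth 8-fold summits were found in 16.3% of cases, so a site called in 1 library alone was not shown to be absent from the other.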

Other observations

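The windows, the test of neighbouring peaks and the comparison of sex chromosomes in this part were chosen after seeing the data.

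Of 15042 windows of 100 kb that held a union peak, the median held 4 and 1183 held 10 or more; whether this exceeds chance placement was not tested. The windows with the most peaks past the rule as higher held several peaks each and none past the rule as lower. On chromosome 8 from 129100001 to 129200000, 12 of 19 union peaks were higher, and the reads of all its peaks together had a ratio of 2.22 (exact 95% interval 1.90 to 2.59). On chromosome 11 from 99000001 to 99100000, 11 of 16 were higher with a ratio of 2.14 (1.92 to 2.38), and on chromosome 1 from 53900001 to 54000000, 11 of 17 with a ratio of 1.86 (1.66 to 2.08). A pair of neighbouring windows on chromosome 1, from 163200001 to 163300000 and from 163300001 to 163400000, had 10 of 17 and 10 of 13 peaks higher, with ratios of 2.54 (2.25 to 2.85) and 2.46 (2.18 to 2.78). These 5 windows were picked out of 15042 for their higher peaks, so ratios over 1 follow from the choice, and all window ratios use scaling by total reads. In each of them at least 94.0% of the reads had the top mapping quality.

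The 5 windows ranked first by lower peaks held 3 or 4 such peaks each, and they did not share a direction. Other windows may also hold 3, so those with 3 are not shown to rank above the rest. On chromosome 3 from 145800001 to 145900000, 4 of 8 union peaks were lower and 1 higher, with a ratio of 0.894 (0.744 to 1.07), and on chromosome 16 from 45300001 to 45400000, 4 of 17 were lower and 5 higher, with a ratio of 1.13 (0.994 to 1.28). On chromosome 1 from 153900001 to 154000000, 3 of 8 were lower with a ratio of 1.44 (1.27 to 1.65). On chromosome 1 from 180800001 to 180900000, 3 of 4 union peaks were lower, with 37 reads against 130 and a ratio of 0.42 (0.283 to 0.609). On chromosome 1 from 131500001 to 131600000, 3 of 5 were lower with a ratio of 0.621 (0.479 to 0.801). The window with the most peaks of all, on chromosome 11 from 3000001 to 3100000, held 62 union peaks with 1 higher and 1 lower, a ratio of 0.912 (0.881 to 0.943), and only 68.3% of its reads had the top mapping quality. The next, on chromosome 2 from 77700001 to 77800000, held 38 with none past the rule, a ratio of 1.25 (1.19 to 1.31) and 69.5% of reads at the top quality. Both ratios lie below the median ratio of 1.34 at shared peaks. With scaling to that median the chromosome 2 window also falls under 1, and the chromosome 11 window, already under 1, falls further.

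One hypothesis is that changes are grouped along chromosomes. Over 21656 pairs of neighbouring union peaks between 1 and 10 kb apart the log2 ratios correlated with r = 0.0371, above the highest of 100 shuffles within classes of strength (0.0188), so a weak grouping may be present. These are correlations across peaks, which are not independent replicates. Where both neighbours passed the rule, 84.5% of pairs went the same way, against 83.2% for independent neighbours. A shared local background stays open as a part of it, since the correlation was 0.0199 after the ratio of the reads between peaks was regressed out.

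The X chromosome took a larger share of reads in the TGF-β plus IL-4 library, with a log2 ratio of 0.17 over all reads and 0.24 outside peaks, where the 19 autosomes lay between -0.09 and 0.09. Reads per kb on X were 0.449 times those on autosomes in the library with no treatment named and 0.509 times in the other, and on Y 0.417 and 0.475 times. More female cells in the TGF-β plus IL-4 library would lower the share of Y, which was higher instead, with a log2 ratio of 0.18 (95% interval 0.12 to 0.24). A trend in which chromosomes with fewer peaks take more background reads did not pass the test over the 19 autosomes (Pearson r = -0.361, permutation p = 0.128, and Spearman rho = -0.311, permutation p = 0.192). The trend stays open only because X, with 9.06 peaks per Mb, lies outside the range of the autosomes. Extended to X it gave 0.078, with a standard error of prediction of 0.070. The measured value lies 2.32 of these standard errors above it, so both a rule written before this test and the one that replaced it after the result was seen would place X too far from a straight trend. What keeps the trend open is that its shape outside the range of the autosomes is assumed. A difference between the libraries in how sequence composition or closed chromatin was recovered was not tested, and neither was an effect of the stimulation.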
